A study of Mus musculus with 2 samples.

How the data were processed

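DNase-seq sequences the ends that the enzyme DNase I leaves in nuclei, so that cuts pile up where chromatin is accessible. It was run on thymus tissue, the organ in which T cells mature, of female B6CASTF1/J mice, which are hybrids of the B6 and CAST strains, aged 18 to 20 months per the labels. There were 2 libraries in 1 group, numbered as biological replicates 1 and 2 in the labels. Both carry the same donor record and separate biosample records, and nothing states that separate animals were used, so the spread between them may be technical. No younger age, other sex or other tissue was compared here.

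Each library came with 2 peak lists, a footprint list and a list of base runs with a false discovery rate, all on the mm10 build per the file notes. The file notes name the library behind each file and show that files were made per library, without pooling. The peak caller, its version, its thresholds and the aligner are not given in the sources used here. The peak lists hold 1 signal value per peak as the authors deposited it, with no stated scale. All signal values of a library were whole multiples of 1 step within a tolerance of 0.1 steps, 0.00895 in replicate 1 and 0.00652 in replicate 2. The step resembles 1 cut or read scaled by 1 factor per library, and log2 ratios between libraries are therefore given after subtracting the median log2 ratio, except where the median itself is stated. Signals given per library or as mean ± SD are as deposited, so that their SD includes any difference in scale. The q-values per base run that the authors deposited ran from 0 to 0.0499 in both libraries. Every footprint carried the constant 0.01, so footprints could not be ranked and only their positions were used.

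The shorter peak list of each library was taken as the main list, before any comparison was computed. Every peak in it touched bases with a q-value of 0.001 or lower, against 67.4% and 65.3% of peaks in the longer list of replicates 1 and 2. The longer list was compared separately. Sequencing depth is not stated. If both signals were scaled to the same total, the steps would give replicate 2 a depth 1.37 times that of replicate 1. The median peak held 186 steps in replicate 1 and 219 in replicate 2, which would give a counting error of 7.33% and 6.76% if a step were 1 independent cut.

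Coordinates and sequence came from the GRCm38 assembly, whose chromosome names and lengths fit mm10, and genes from the GENCODE vM21 basic annotation, with 21827 protein-coding genes and 41406 start sites. Coordinates are given counted from 1. A peak was placed by its centre: within 1 kb of a start site of a protein-coding gene (promoter), otherwise in an exon, an intron or between genes. Peaks and footprints were shared if they overlapped by at least 1 bp. Chance overlap was taken after peaks were placed at random on their own chromosome, and footprints at random within the peaks of their own library, with bedtools 2.31.1. Signals were compared across 1-to-1 pairs of overlapping peaks by Spearman and Pearson correlation. These run across peaks, which are not replicates, so no p-value was attached.

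Before the data were examined, 14 gene lists with 220 genes were fixed, of which 219 were found in the annotation. They cover T cells and thymocytes, thymic epithelium, B cells, myeloid and dendritic cells, fibroblasts, adipocytes, endothelium, erythroid cells, hepatocytes, neurons, skeletal muscle, housekeeping genes, T cell exhaustion and ageing, and senescence with the cell cycle. A gene counted as open if a peak of the main list lay within 1 kb of any of its start sites in both libraries. Shares were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 14 lists. Numbers of peaks in the gene and 10 kb on each side were compared by the list median against 10000 random lists of the same size, matched on gene length in 10 bins, a permutation test over genes; lists matched on promoter CpG content, in 20 bins, were drawn in the same way. The smallest two-sided p such draws can give is 0.0002. Genes, not animals, are the unit of these tests, so they describe lists within these 2 libraries. The genes named were fixed by rule: per list the 3 with the highest mean promoter signal and up to 3 without a promoter peak in either library (all of them for T cells), the 5 list genes whose promoter signal differed most between libraries, among those with a peak in both, and the 10 protein-coding genes with the most peaks per 100 kb of span, among spans of at least 20 kb. Some genes that the rule names are not reported here.

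Footprints were extended by 5 bp on each side and searched on both strands for 24 consensus sequences, also fixed before the data were examined. A consensus stands for a family of factors. The background was a window of the same width at least 100 bp away, inside the longer peak list of the same library and outside all footprints; the 78.2% and 81.9% of footprints in replicates 1 and 2 with such a window were searched, and the others were left out. Shares were compared by Fisher's exact test with adjustment over the 24 families in each library, and a family was called only if it passed 0.05 in the same direction in both. The ratio has 0.5 added to each count. Neighbouring footprints are not independent, which makes these p-values too small.

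For receptor loci, V, D, J and C segments were taken from the annotation, with 10 kb on each side. Segments over 1 Mb from the rest were left out, a choice made after seeing that 2 Igk segments stretched that locus. A segment had a peak if one lay within 500 bp. Y peaks were searched against the other chromosomes with BLAST+ 2.17.0, a match being 95% identity over 80% of the peak. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9. Intervals are exact 95% binomial (Clopper-Pearson) or, for motif ratios, 95% on the log scale, and cover counting error only.

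The overlap, list, log ratio and motif steps were tested on simulated data; correlations, densities, segment calls, sequence matches and lists matched on CpG content or start sites were not. With 21827 genes, lists whose open share was raised from 55% to 95% were found in 97.5% of draws and unchanged lists were called in 1.6%. Lists of peak numbers raised 4-fold plus 2 peaks were found in 100% of draws and 0.5% of unchanged lists were called. Smaller raises were not simulated. A shift of 0.5 on the log2 scale was found for 73.8% of lists and 3% of unshifted lists were called. A motif planted in 10.0% of 50000 sequences was recovered in 9.99% after subtracting the background share. Shares as low as those in the footprints were not simulated. Alternatives covered the overlap needed, the peak threshold and list, the promoter window, the flank, the background and edges of footprints, and leaving out either library; alternatives added later are named in the closing section.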

Results

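DNase I hypersensitivity was mapped in the thymus of aged female B6CASTF1/J mice in 2 libraries of 1 group. The main list held 50648 peaks in replicate 1 and 49872 in replicate 2, which covered 10672183 and 10958010 bp. The longer lists held 77453 and 79004 peaks. Short protected stretches within accessible DNA, called footprints, numbered 223227 and 247677, with a median length of 10 bp in both libraries. The median peak signal, in the units of the deposited lists, was 1.66 in replicate 1 and 1.43 in replicate 2. Read depth is unknown, and values are means ± SD over the 2 libraries unless said otherwise. A promoter peak is one of the main list unless the longer list is named. Promoter signal is that of the strongest such peak in each library, whose position can differ between libraries. A peak near start sites of several genes counted for each of them, so a signal can come from the promoter of a neighbour.

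Promoters of T cell genes were open in both libraries for 32 of 36 genes (88.9%, exact 95% interval 73.9% to 96.9%), against 53.5% of all other protein-coding genes (Fisher's exact test, adjusted p = 0.000153). The highest promoter signals in the list included those at Ets1, a transcription factor of lymphocytes (12.7 ± 2.20, n = 2), and at Satb1, a chromatin organiser in thymocytes (10.01 ± 0.229). On GRCm38 these peaks lay at chromosome 9, 32695861 to 32696080, and at chromosome 17, 51833081 to 51833360, as called in replicate 1. Trat1, which encodes an adaptor of the T cell receptor, had no promoter peak in either library. Cd2, Cd4 and Dntt, named here after their values were seen, had a promoter peak in replicate 2 but not in the main list of replicate 1, whose longer list held a peak there with signals of 2.22, 1.38 and 1.70. Among 10000 random lists matched on promoter CpG content, with a median of 36.1% open, none reached the share of the T cell list (permutation test over genes, adjusted p = 0.00280).

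Housekeeping genes and genes of the cell cycle were also open. All 14 housekeeping genes (100%, exact interval from 76.8%, adjusted p = 0.000839) and all 12 genes of senescence and the cell cycle (100%, exact interval from 73.5%, adjusted p = 0.00183) had a promoter peak in both libraries. Promoter signals reached 18.3 ± 0.373 at the cytoskeletal gene Actb, 17.7 ± 0.354 at the ribosomal gene Rplp0 and 13.4 ± 1.77 at Ppia, which encodes cyclophilin A. Among cell cycle genes, the replication genes Mcm2 and Pcna had 12.8 ± 2.33 and 11.9 ± 0.916, and Top2a, which encodes a topoisomerase of dividing cells, had 8.83 ± 1.69. By median promoter signal, only the housekeeping list stood apart from random lists (median 11.0, permutation test, adjusted p = 0.00280); the T cell list, with a median of 4.69, lay at percentile 99.3 (adjusted p = 0.0980).

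Promoters of other cell types were open less often than those of other genes in 6 lists (Fisher's exact test). Of hepatocyte genes 0 of 14 were open in both libraries (exact interval up to 23.2%, adjusted p = 0.000153), with Apob carrying a peak in replicate 1 alone (0.841) and none at Alb, Apoa1 or Ttr, which encode plasma proteins. Of myeloid and dendritic genes 2 of 18 were open (11.1%, exact adjusted p = 0.00155), with values of 1.94 ± 0.510 at the transcription factor gene Cebpb and 0.763 ± 0.0465 at the phagocytosis receptor gene Mertk, and none at Itgax, Csf1r or Lyz2. The strongest Mertk peaks of the 2 libraries did not overlap. Itgam had a peak in the main list of replicate 1 only. Skeletal muscle genes were open for 2 of 12 (16.7%, exact adjusted p = 0.0389), Mylpf (8.35 ± 1.98) and Tnni2 (1.90 ± 0.609), which encode parts of the contractile apparatus, and not at the myogenic factor genes Myod1, Myog and Myf5. B cell genes were open for 4 of 16 (25%, exact adjusted p = 0.0463), among them Ebf1 (4.05 ± 0.198), Pou2af1 (3.21 ± 0.895) and Cr2 (2.96 ± 0.298), and not at Cd79a or Cd79b. Fibroblast genes were open for 3 of 14 (21.4%, exact adjusted p = 0.0463), namely Col1a1 (2.98 ± 1.19), Pdgfra (1.49 ± 0.629) and Fbln1 (1.19 ± 0.397), and not at the collagen genes Col1a2, Col3a1 and Col6a1. Erythroid genes were open for 2 of 11 (18.2%, exact adjusted p = 0.0463), among them Epor (1.24 ± 0.228), and not at Gata1, Klf1 or Hbb-bs. At Klf1, base runs within 1 kb of a start site had q-values down to 1.23e-07 and 0.000714 in replicates 1 and 2, without a listed peak.

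Thymic epithelial genes were open for 6 of 18 (33.3%, adjusted p = 0.122), which did not pass the exact test. Within that list, signals were 8.49 ± 1.62 at Ccl25, a chemokine that attracts T cell progenitors, 3.76 ± 1.19 at Aire, which drives the display of tissue antigens, and 3.52 ± 0.0817 at Cldn4. The Ccl25 peak lay at the upstream end of the annotated gene, and whether another gene starts there was not checked. No promoter peak was listed at Foxn1, Psmb11 or Fezf2. Adipocyte genes (4 of 14, adjusted p = 0.122), endothelial genes (4 of 12, 0.246), neuronal genes (3 of 12, 0.110) and genes of T cell exhaustion and ageing (6 of 16, 0.236) also did not pass the exact test. Their highest promoter signals were at the lipase genes Pnpla2 (8.999 ± 1.57) and Lipe (6.44 ± 0.292) and at Cebpa (2.31 ± 0.581), at Pecam1 (2.74 ± 0.466), Erg (1.82 ± 0.114) and Egfl7 (1.57 ± 0.476), at Syn1 (1.72 ± 0.131), Grin1 (1.01 ± 0.245) and Map2 (0.559 ± 0.00656), and at Prf1 (2.82 ± 0.464), Lag3 (2.04 ± 0.140) and Ikzf2 (1.88 ± 0.0752). The strongest Ikzf2 peaks of the 2 libraries did not overlap. No promoter peak was listed in either library at Adipoq, Fabp4, Plin1, Cdh5, Tek, Tie1, Snap25, Syt1, Rbfox3, Havcr2, Gzmb or Gzmk. The longer lists held peaks in both libraries at Itgam (1.18 in replicate 1 and 1.29 in replicate 2), Lyz2 (0.421 and 0.528), Cd79b (0.770 and 1.28), Apob (0.841 and 0.404), Snap25 (0.331 and 0.274) and Syt1 (0.224 and 0.287), and in 1 library at Cd79a, Col1a2 and Myf5. The B cell call was lost in each library alone (adjusted p = 0.107 in replicate 1 and 0.454 in replicate 2) and with other windows, thresholds or lists of peaks, with 43.8% open within 2500 bp (0.452) and 56.3% in the longer list (adjusted p = 1), the fibroblast call in replicate 1 alone (0.0917) and the erythroid call in replicate 2 alone (0.0503) and within 2500 bp (0.126), all by exact tests. With lists matched on the number of start sites, the erythroid call was lost (permutation test over genes, adjusted p = 0.113), the B cell call held (0.0373) and the neuronal list passed (0.0436). The muscle call was lost for the stronger 50% of peaks (0.0568) and in the longer list (0.0556), also by exact tests. With lists matched on CpG content, every call but that of T cells was lost (adjusted p from 0.347 to 0.744 for the 8 others), the B cell and erythroid shares lay above their matched medians of 18.8% and 9.09%, and the neuronal list stood lower, with 25% against a median of 66.7% (permutation test over genes, adjusted p = 0.0182).

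**Figure D1:**
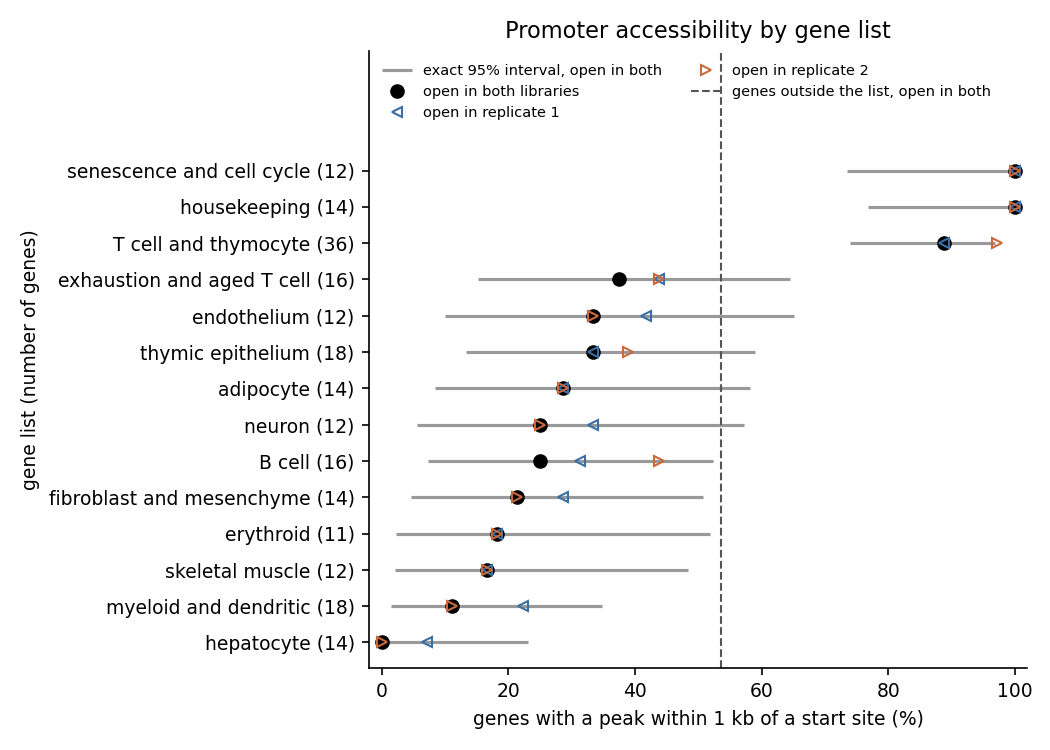
Share of genes with a peak within 1 kb of a start site, in percent, for the 14 gene lists; black points stand for genes open in both libraries with exact 95% intervals, open triangles for each library, and the dashed line for genes outside the list. The T cell list stands at 88.9% and the hepatocyte list at 0, with the line at 53.5%.

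T cell genes also carried more peaks along their length. The median T cell gene had 8.75 peaks in its span and 10 kb on each side, against 2.25 in random lists of genes of like length (central 95% of lists 1.25 to 3.5, permutation test, adjusted p = 0.00280). The medians were 7 peaks in replicate 1 and 9.5 in replicate 2, and a median of 6 peaks per gene lay over 1 kb from start sites. With peaks within 500 bp joined, an alternative chosen after seeing the data, the median was 5.5 (permutation test, adjusted p = 0.00280). No other list passed, the nearest being housekeeping genes with a median of 4 (permutation test, adjusted p = 0.0896); these did pass when the flank was left out (adjusted p = 0.0378) or when only the stronger 50% of peaks were counted (0.00420).

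Across all protein-coding genes with spans of at least 20 kb, the densest by the mean of both libraries was Tap2, a peptide transporter gene of antigen presentation, with 94.5 peaks per 100 kb (24 peaks in replicate 1 and 38 in replicate 2). Its neighbour Psmb8, which encodes an immunoproteasome subunit, had 69.5. Cd8b1, which encodes a chain of the CD8 co-receptor, had 73.5 and was the only gene of the T cell list among the 10 densest. The others were the histone demethylase gene Kdm6b (88.1) with its neighbour Tmem88 (71.4), the neighbours Atp5d (86.4) and Midn (86.4), Mpv17l2 (76.2), Zfp36l2 (72.9), which encodes a protein that promotes decay of messenger RNA, and Grk2 (69.6), which encodes a receptor kinase. Neighbouring genes share peaks because of the flanks. Peak numbers, and with them the order, differed between libraries: Mpv17l2 was denser than Tap2 in replicate 1, and Kdm6b and Atp5d were in replicate 2. Cd8b1 had 14 and 37 peaks; with peaks joined in that way, Cd8b1 had 10 and 8, covering 3242 and 9376 bp.

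The antigen receptor loci differed in peak density. The Tcra and Tcrd locus, which holds the genes of the α and δ chains, had 5.04 ± 0.195 peaks per 100 kb (89 and 94 peaks), against 1.84 over the whole genome. Tcrb had 2.84 ± 0.309 and Tcrg 2.82 ± 0.363. Among immunoglobulin loci, the heavy chain locus Igh had 2.65 ± 0.229 (78 and 69 peaks), the λ light chain locus Igl 1.14 ± 0.323, and the κ light chain locus Igk 0.0783 ± 0.0222, with 3 peaks in replicate 1 and 2 in replicate 2 over 3191 kb. These are densities with SD over 2 libraries, and no test was run between loci.

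The strongest peak of the Tcra and Tcrd locus lay at chromosome 14, 54227421 to 54227740, in replicate 1 (signal 13.9) and from 54227401 in replicate 2 (17.9). It lay outside annotated segments, 3214 bp beyond the constant segment Trac, where the textbook enhancer of the α chain gene lies. In Tcrb the strongest peak was the same interval in both libraries, chromosome 6, 41554401 to 41554640 (8.21 and 10.4), 3050 bp from the segment Trbv31, where the textbook β chain enhancer lies. Variable segments with a peak within 500 bp in both libraries numbered 36 of 136 in Tcra and Tcrd (26.5%), 7 of 35 in Tcrb, 1 of 7 in Tcrg and 28 of 196 in Igh (14.3%), against 0 of 176 in Igk and 0 of 3 in Igl. Of the 62 joining segments of Tcra and Tcrd, 1 had a peak in both libraries. Mappability of repeated segments was not analysed here.

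Motif sites were counted in the footprints that had a matched background window, 174494 in replicate 1 (78.2%) and 202845 in replicate 2 (81.9%). Sites of CTCF, the insulator protein, were found in 0.548% ± 0.0954 of these footprints and 0.00722% ± 0.00114 of background windows, a ratio of 75.2 ± 24.5 (n = 2). Ratios were 71.5 ± 26.5 for NRF1, 16.01 ± 6.46 for the cyclic AMP response element, 13.96 ± 1.87 for the SP and KLF family and 3.30 ± 0.0690 for YY1. Only 2 background windows in replicate 1 and 4 in replicate 2 held an NRF1 site, against 14 and 13 for CTCF. The size of the NRF1 ratio is therefore uncertain, with intervals of 25.9 to 314 in replicate 1 and 20.8 to 134 in replicate 2. Among factors of T cell development, ratios were 2.16 ± 0.527 for TCF7 and LEF1, 1.71 ± 0.190 for RUNX, 1.18 ± 0.0138 for ETS, 1.18 ± 0.00342 for Ikaros and 1.12 ± 0.0214 for the E-box with core CAGCTG, listed here under E2A and HEB. The EBF family, best known from B cells, had 1.68 ± 0.178. These 11 families of the 24 were raised in both libraries by Fisher's exact test, with adjusted p of at most 0.00109.

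Sites lowered in both libraries were those of the E-box with core CAGGTG (0.889 ± 0.00568), NF-Y (0.747 ± 0.00434), AP-1 (0.657 ± 0.0246), GATA (0.602 ± 0.0455) and PU.1 (0.568 ± 0.0126), the last a factor of myeloid and B cells. The E-box cores CAGCTG and CAGGTG thus went in opposite directions, and which factors bind each was not tested. The 8 other families were not called, among them HNF1 and HNF4, known from hepatocytes, MEF2, known from muscle, and REST. Several had few sites, with HNF1 in no footprint, HNF4 in 22 and 31 and MEF2 in 16 and 16 in replicates 1 and 2. MEF2 was raised in both libraries against shuffled sequence (6.60). Footprint sequence was richer in G and C than background windows (62.9% against 57.9% in replicate 1, 63.0% against 57.6% in replicate 2). Reversed consensus sequences keep the bases but, except for SP and KLF, not the site. They gave ratios of 0.589 for PU.1, 0.698 for GATA, 0.629 for AP-1, 0.561 for NF-Y and 1.49 for EBF. The SP and KLF consensus reads nearly the same backwards, so its reversed ratio of 7.50 does not separate base content from the site. Against shuffled sequence the ratios of all 5 lowered families lay above 1 (PU.1 2.59), and the calls of ETS, RUNX, EBF, Ikaros and of E2A and HEB were each lost under 1 or more alternatives. Across alternatives the ratio of CTCF ran from 46.7 to 379, of the cyclic AMP response element from 8.61 to 60.5, of SP and KLF from 8.61 to 42.8, of YY1 from 2.17 to 194, of NRF1 from 21.1 to 560, of ETS from 1.15 to 6.23 and of RUNX from 1.39 to 5.68.

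**Figure D2:**
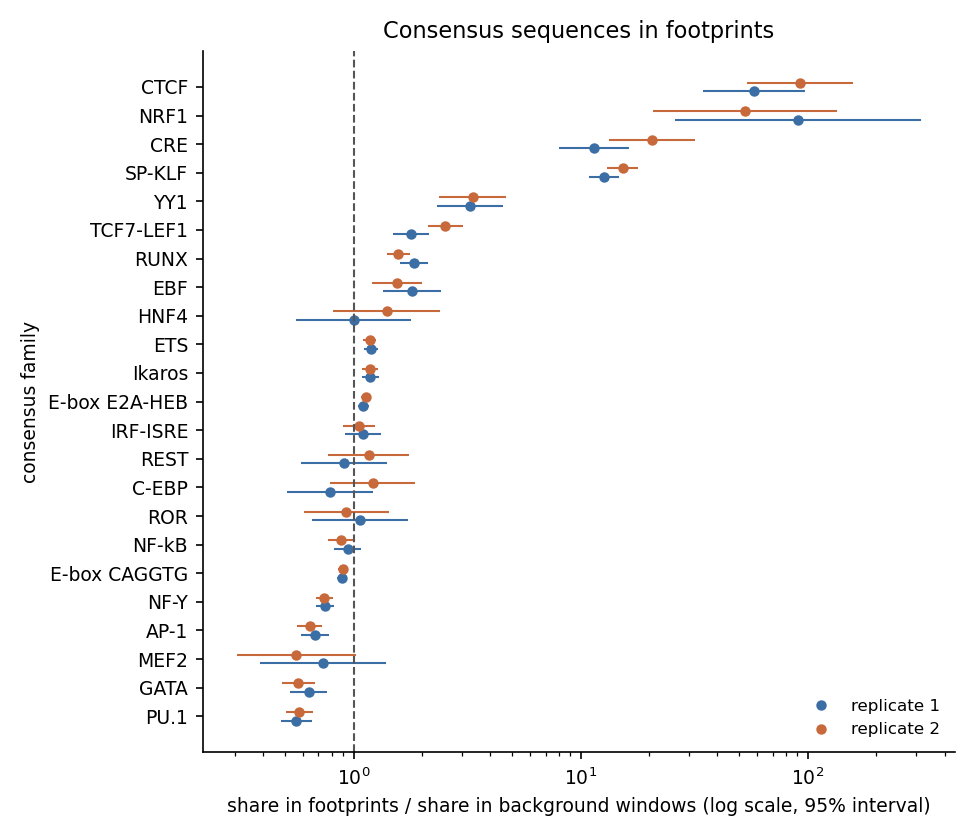
Share of footprints with a consensus site over the share of background windows, on a log axis, for each family and library with 95% intervals, leaving out HNF1, which was found in none of the footprints searched. CTCF and NRF1 stand farthest to the right with mean ratios of 75.2 and 71.5, and PU.1 stands at 0.568.

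Peaks at promoters were the most often shared. Peaks within 1 kb of a start site made up 39.2% ± 0.258 of peaks (n = 2) and 53.1% of the stronger 50%, although such windows hold 1.97% of the genome; 27.4% ± 0.0685 lay in introns, 29.4% ± 0.510 between genes and 4.02% ± 0.321 in exons. Of promoter peaks 88.2% ± 0.483 overlapped a peak of the other library, compared with 73.9% ± 0.662 of intronic, 76.3% ± 2.11 of intergenic and 70.1% ± 3.29 of exonic peaks. The gap between promoters and each other class was larger than the spread between the 2 shares. Both shares count the same overlaps, seen from each library, so this spread is not one between independent replicates. No exact permutation test over 2 libraries can pass a threshold of 0.05. Promoter peaks were also stronger, with median signals of 2.85 and 2.52 in replicates 1 and 2, against 1.34 and 1.15 in introns and 1.40 and 1.15 between genes.

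The libraries shared 79.4% of the peaks of replicate 1 and 80.7% of those of replicate 2 (mean 80.04% ± 0.872), against 0.864% for randomly placed peaks. These shares are 1 comparison read in 2 directions, so the SD is not a spread between replicates. The same holds for the overlaps of the longer lists and of footprints. In the longer lists the shares were 76.0% and 74.5% (mean 75.2% ± 1.09, chance 1.29%). Sharing followed signal, from 44.5% and 53.5% in the weakest quartile of replicates 1 and 2 to 99.2% and 99.4% in the strongest. Of the peaks called in 1 library only, 59.1% in replicate 1 and 45.4% in replicate 2 overlapped the longer list of the other library. Footprints were shared less often (57% and 51.4%, mean 54.2% ± 3.94), against 27.1% and 24.2% when footprints were placed at random in peaks. Territory with a false discovery rate of at most 0.05 spanned 27019070 and 28042163 bp, of which 83.0% and 80.01% was common to both. Across 39252 pairs of peaks, which are not independent replicates, signals correlated with a Spearman rho of 0.922 and a Pearson r of 0.940 on the log2 scale. The log2 ratio of replicate 2 to replicate 1 had a median of -0.17 and an SD of 0.44.

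**Figure D3:**
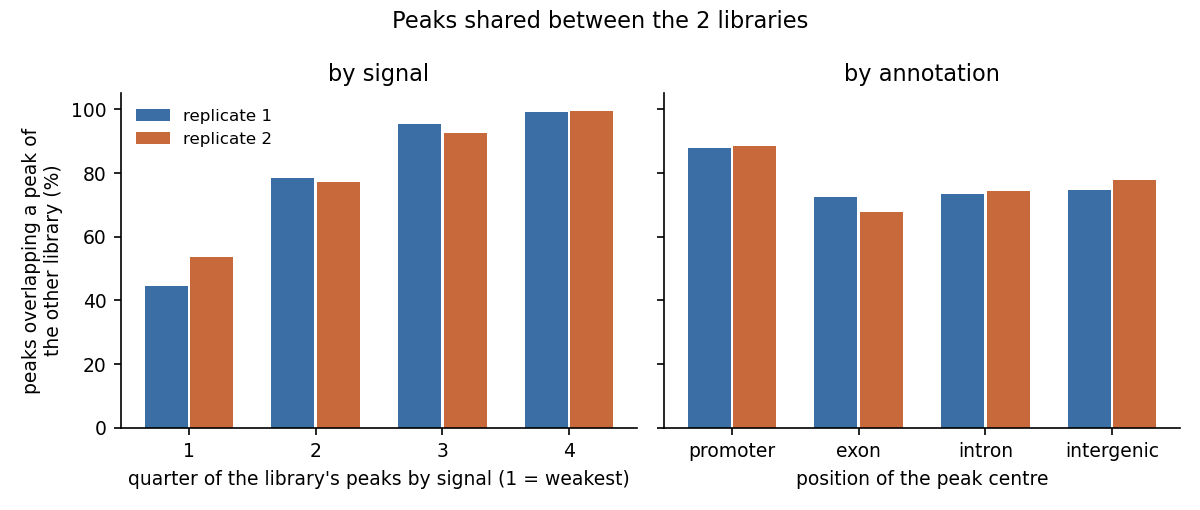
Percent of peaks that overlap a peak of the other library, by quartile of signal (left, 1 is the weakest) and by position (right), with bars for each library. The strongest quartile stands at 99.2% and 99.4% and the weakest at 44.5% and 53.5%.

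Relative to all 57202 paired peaks of the longer lists, replicate 2 had higher signal than replicate 1 near T cell genes. These list ratios thus include weak peaks that the main list leaves out, and they are not limited to promoters. Their sign can differ from that of the promoter: Ets1 had 0.38 against -0.19 at its promoter, and Cd5 had -0.44 against 0.65. Neighbouring genes such as Cd3d and Cd3g may share peaks, so genes need not be independent. The median log2 ratio over 35 T cell genes with paired peaks was 0.24, higher in 33 of 35 genes and above all 10000 random lists of genes. Genes of T cell exhaustion and ageing had 0.27 (9 of 12 genes higher, percentile 99.97). Fibroblast genes had -0.46 (7 of 9 genes lower, percentile 0.12) and erythroid genes -0.41 (5 of 6 lower, percentile 0.8). Hepatocyte genes had -0.33 (6 of 7 lower, percentile 2.22). Their percentile was 8.49 after regression on GC and 2.325 after regression on GC, signal and width. Other lists lay inside the central 95% of random lists, among them B cell genes at 0.09, myeloid genes at -0.01, endothelial genes at -0.13, thymic epithelial genes at -0.14 and housekeeping genes at 0.11 (percentile 93.75, but 98.25 after regression on GC, signal and width). Among promoters of listed genes with a peak of the main list in both libraries, the largest differences were at Pdcd1, which encodes the PD-1 receptor (0.85), Zbtb7b, a factor of CD4 T cells (0.79), the glycolytic gene Pgk1 (0.77), Pou2af1 (0.75) and Pdgfra, a receptor of mesenchymal cells (-0.72). A difference between 1 library and 1 other carries no p-value, and percentiles describe these libraries only.

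**Figure D4:**
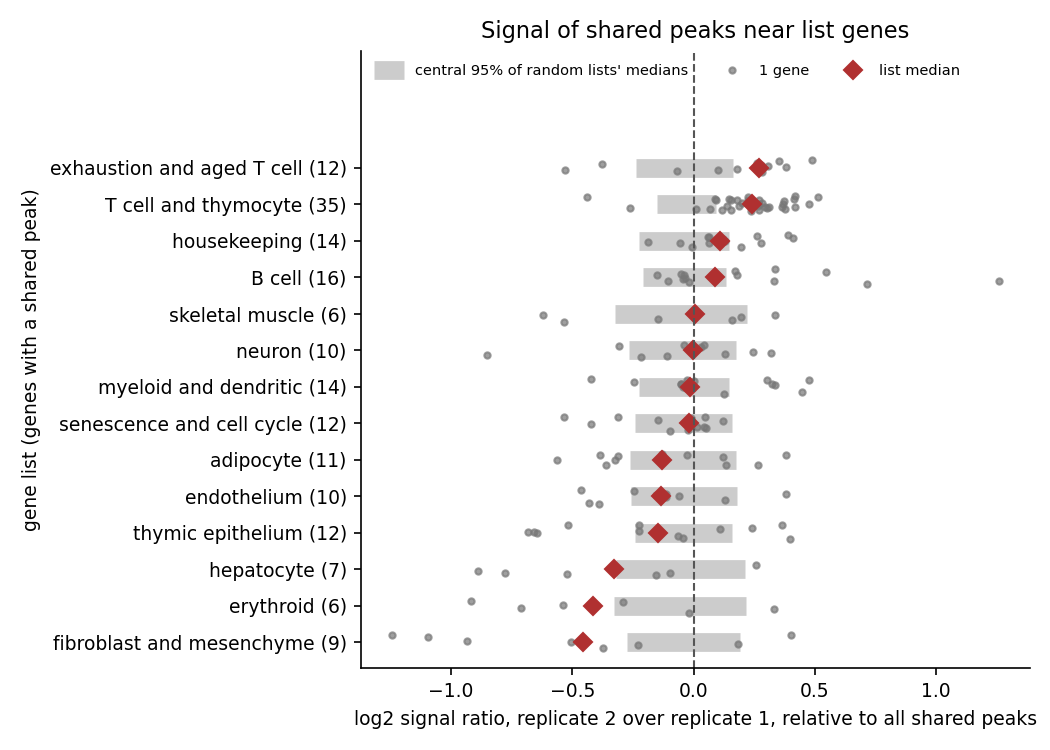
Log2 signal ratio of replicate 2 over replicate 1, relative to all paired peaks of the longer lists. Each grey point stands for 1 gene and the red diamond for the list median. The grey bar spans the central 95% of medians of random lists. The T cell median is 0.24 and the fibroblast median -0.46.

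Peaks were unevenly spread over chromosomes. Chromosome 11 was the densest, with 34.9 ± 1.12 peaks per Mb (n = 2), followed by chromosome 17 (27.7 ± 0.856) and chromosome 19 (27.3 ± 0.0345). The X had 7.78 ± 0.616 peaks per Mb, and its density was 0.392 ± 0.0274 of that of the autosomes. The strongest peaks of both libraries lay near the end of the X, at 169997941 to 169998240 in replicate 1 (signal 73.7) and at 169997961 to 169998420 in replicate 2 (109.0), 11568 and 11468 bp from the nearest start site, that of Gm21887. The Y, which these female mice lack, carried 19 and 35 peaks, of which 11 and 21 lay between 90717601 and 90744820 with signals up to 6.62 and 11.97. The 8 and 14 other Y peaks had signals of at most 0.689 and 0.476. Both ends lie near the textbook boundary of the pseudoautosomal region, which the X and Y share, and how reads that map to several places were treated is not given in the sources used here.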

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

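Alternatives chosen only after the data were seen were the stronger 50% against the whole list, the other library's longer list, footprints in peaks of both libraries, joined peaks, matching on signal, regressions on GC, signal and width, a background within false discovery rate territory, and footprints limited to the shorter list or to both libraries.

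Peak overlap of 80.04% moved to 69.3% with 50% reciprocal overlap, 77.1% by peak centre, 85.9% for the stronger 50% of both lists, 96.6% for the stronger 50% against the whole list and 90.3% against the longer list. In the longer lists these settings gave 63.5% (reciprocal), 85.9% (stronger 50%) and 95.2% (against the whole list), and for footprints 40.2% (reciprocal) and 63.9% (in peaks of both libraries). The stronger 50% of footprints was not run, since all carry 1 value. Promoter share moved to 31.1% within 500 bp, 45.9% within 2500 bp, 53.1% for the stronger 50% and 31.1% in the longer list. Gene body lists past the test were 2 without the flank and 2 for the stronger 50%, housekeeping being added to T cells. Raised motif families numbered 17 against shuffled sequence. In the longer list the X-to-autosome ratio was 0.420 and the T cell receptor loci held 190 peaks, against a mean of 116.5 in the main list. Mean densities per 100 kb there were 7.85 in Tcra and Tcrd, 5.53 in Tcrb and 4.88 in Tcrg. For immunoglobulin loci they were 4.59 in Igh, 2.28 in Igl and 0.219 in Igk.

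Reversed motif ratios were, against shuffled sequence, 1.20 for CAGGTG, 1.03 for GATA, 1.34 for AP-1, 3.95 for NF-Y and 2.59 for PU.1; without extension, 1.12 for CAGGTG and 0.945 for Ikaros; and against false discovery rate territory, 1.12 for CAGGTG, 1.91 for NF-Y and 0.996 for Ikaros. Calls were also lost without extension for ETS (1.17, against 1.18 in the main setting), RUNX (1.39) and EBF (1.16). With 10 bp they were lost for EBF (1.26), E2A and HEB (1.07) and CAGGTG (0.957). Background 200 bp away lost those of Ikaros (1.04) and NF-Y (0.976). Shared footprints lost those of EBF (1.33), Ikaros (1.06) and E2A and HEB (1.04). The shorter list lost that of NF-Y (0.990), and false discovery rate territory that of PU.1 (0.826). The cause was not tested. Leaving out each library in turn gave a promoter share of 39.0% to 39.4%, 7 to 7 promoter lists past the test against 9, 1 to 1 gene body list and 11 to 11 motif families. Overlaps need both libraries and gave no such value. Across the alternatives for windows, thresholds, peak lists and libraries, 11 single list values lost their call, 6 of them for B cells, and 1 list, neurons, gained one; matching on CpG content or start sites is not in this count. Of the replicate ratios, hepatocytes lay at percentile 4.015 with lists matched on signal and 8.49 after regression on GC. After regression on GC, signal and width they lay at 2.325. No paired analysis was possible because there is only 1 group. Read depth is unknown. Peak overlap was higher among stronger peaks, footprints could not be ranked, and what limits the overlap values was not tested.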

Other observations

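The additional genes named here, and the tests of both parts of the Y peaks, were chosen only after the values were seen. Promoter signals of further T cell genes ranged widely. Means were 8.95 ± 0.700 (SD, n = 2) at Cd3g, a chain of the receptor complex, 8.46 ± 0.836 at the co-receptor gene Cd8a, 8.44 ± 0.733 at the kinase gene Lck, 6.47 ± 0.417 at the recombinase gene Rag1 and 4.91 ± 0.266 at its partner Rag2, against 3.36 ± 0.285 at Ptcra, which encodes the surrogate α chain, and 2.68 ± 0.0975 at Cd3d. Transcription factors of the lineage had 8.84 ± 0.726 at Gata3, 7.25 ± 0.582 at Bcl11b and 5.94 ± 0.0646 at Tcf7. The interleukin receptor gene Il7r had 0.844 ± 0.0423. The span of Tcf7 held 7 peaks in replicate 1 and 43 in replicate 2, and that of Cdkn1a, an inhibitor of the cell cycle, 4 and 30. Their promoter signals were nearly level, with 5.90 and 5.99 at Tcf7 and 2.19 and 2.26 at Cdkn1a. Nearby peaks were not joined for these counts, so they need not reflect more accessible sites.

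Among genes of senescence, Cdkn2a had the lowest promoter signal of its list, 0.795 ± 0.267, at the start site farthest upstream, which serves p19Arf and not p16, compared with 2.09 ± 0.468 at Cdkn2b and 7.85 ± 0.0969 at Trp53. The strongest Trp53 promoter peaks of the 2 libraries did not overlap, so the SD does not describe 1 site. The proliferation gene Mki67 had 5.16 ± 0.125. Among thymic epithelial genes, Prss16, a protease of the cortex, had 2.46 ± 0.603 and Epcam 1.39 ± 0.355, and the keratin genes Krt5, Krt8 and Krt14 had no promoter peak in the main lists (Krt8 had 0.412 in the longer list of replicate 1). Foxn1, without a promoter peak, had 3 peaks in its span and flanks in each library. Foxp3 and Il2ra, genes of regulatory T cells, had no promoter peak in the main lists, 0.718 and 0.724 in the longer list of replicate 2, and 2 and 5 span peaks in replicate 1, with 3 and 8 in replicate 2. B cell genes with a promoter peak in the main list of 1 library were Pax5, Blnk and Ms4a1 in replicate 2 and Cd72 in replicate 1. The strongest promoter peaks of autosomes included Dynlt1b (59.7 in replicate 1 and 57.2 in replicate 2), Hjurp (38.7 and 28.6), Mplkip (33.2 and 34.7) and Dnpep (30.5 and 37.2).

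Open promoters of T cell genes were set against features that could raise any list. Among 10000 lists matched on promoter CpG content the T cell share of 88.9% lay at percentile 100, and among lists matched on the number of start sites at percentile 100 as well, which argues against either feature as the whole cause. No biological explanation was tested, since the design holds 1 tissue and 1 age.

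Higher signal of replicate 2 near T cell genes was set against depth and base composition. The list stayed at percentile 100 when random lists were matched on mean signal and at percentile 100 after regression on GC content, so neither accounts for all of it. A larger share of T lineage nuclei in replicate 2 would lower the lists of the 5 other cell types. Of these, 4 of 5 lay below the median of all paired peaks of the longer lists, B cells lying above it. The myeloid list, counted as lower at -0.01, lay above the median of random lists (-0.03) and at 0.02 after regression on GC, so the count rests on a value near 0 and a larger share cannot be told apart from other differences. A difference between tissue pieces or animals may be the source and was not tested.

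Peaks on the Y in female tissue were set against male cells and shared sequence. None of the promoters of Ddx3y, Uty, Kdm5d and Eif2s3y had a peak in either longer list (0 of 4), which argues against male cells. For sequence matches the Y peaks of both libraries were pooled, 54 in all, so a site called in both can count more than once. Of these pooled peaks 57.4% matched another chromosome at 95% identity over 80% of their length, against 25.5% of random Y windows. For peaks away from the group near the end of the Y the share was 100%, so reads from other chromosomes may account for those. In the end group it was 28.1%, close to random windows, with its 9 matches at X 169986883 to 170022339, where the strongest peaks of both libraries lie. Most of the end group is thus without a match at that identity, and its origin stays open, since it lies near the textbook pseudoautosomal boundary and the treatment of reads that map to several places is not given in the sources used here.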
